A study of Mus musculus with 24 samples.

How the data were processed

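Liver tissue from 24 mice was profiled, 6 normal controls and 18 model mice, with 1 library per mouse. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was captured on oligo(dT) beads and copied into double-stranded DNA, and adaptor-ligated fragments were amplified, circularised and copied into DNA nanoballs for sequencing. The protocol names no step that marks the strand. The deposited table holds raw read counts per Ensembl gene, and per the file headers it has the columns of a read-counting program, with the gene's exon positions, strand and summed exon length. The deposited Length column, a whole number of bases with another unit than the counts, was used only to describe genes. Per the submitters' processing notes the genome build was GRCm39. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here, so how reads of overlapping and near-identical genes were assigned is unknown. Capture by oligo(dT) favours polyadenylated transcripts. Fragments carried no molecular identifiers that the sources name, so counting intervals cover counting error only.

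The table listed 78298 gene IDs, of which 51498 matched a symbol in a reference table of gene names; these took 99.6% of counts. The reference annotation belongs to an earlier build and was used for names alone, and coordinates are those of the deposited table, from the first to the last exon of the gene, 1-based in GRCm39. For 58 symbols shared by more than 1 ID, the ID with the most counts kept the symbol. Library totals were 31.6 M to 58.4 M counts, and the lowest level that 3 counts stand for lay between 0.0514 and 0.0949 CPM. No 2 libraries of a group were alike within sampling noise: over 168 pairs the smallest chi-square per degree of freedom was 19.0.

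Groups came from the labels. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM factors, the default expression filter by group and all 24 libraries in a design with the group alone. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, and a second count required a fold change of at least 2. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. On simulated counts of the real means and library sizes (6 against 18 libraries, 17199 genes), the test found 81 of 100 genes changed 2-fold and 57 of 100 changed 1.5-fold, with 5 false calls of 143. Few genes were changed there, as many up as down, and genes varied independently, so these rates may not carry over to the real data. TMM factors averaged 0.843 ± 0.0285 in controls and 1.06 ± 0.061 in model mice, so library totals alone shift all fold changes upwards.

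A set of 37 gene lists covering pathways, liver and immune cell types and checks was fixed before the data were examined, as were the tests, the alternatives and the rule for genes named. The lists are background knowledge and none was chosen on these libraries. Of them, 35 had at least 3 tested members and were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry. A list's score is the mean log2 CPM of its tested members in a mouse, and groups were compared by a two-sided exact permutation test over 134596 divisions of the mice. The same test on absolute deviations from the group median compared spreads. For 8 relations fixed in advance, Pearson and Spearman correlations over the 18 model mice had two-sided permutation p-values from 100000 resamples. Benjamini-Hochberg adjustment ran within each family. Scores, correlations and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

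The genes named in full follow a rule: the 6 highest and 6 lowest fold changes among called genes with a mean of at least 5 CPM and a proper symbol, the 2 called members with the largest change in each pathway or cell type list, and the most abundant member of each check list. Some list members, 1 of them named by the rule, are not reported here. Other list members are named as examples of their list, chosen after their values were seen. For genes with 1 to 3 control counts a ratio of pooled counts with an exact 95% binomial interval is given. The ratio and its interval are scaled by library totals without TMM factors, which shifts them upwards. The edgeR fold change with TMM factors is given beside them. Alternatives were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, no expression filter, a filter of 1 CPM in 6 libraries, a threshold of 0.01, counts thinned to the smallest library, removal of mitochondrial and the 20 most abundant genes, 20 draws of 6 model libraries, the replicate number as a block, and each library left out in turn. Scores were repeated with a prior count of 0.5, the median over members and library totals. After seeing the data, a clock covariate, a comparison with control 6 alone and scores without model 10 were added. The clock index is the mean log2 CPM of clock genes that peak towards evening minus that of genes that peak towards morning. Of the controls only 1, control 6, lay in the model mice's range of this index. Effects adjusted for it therefore rest largely on that mouse and on a linear fit, and have wide errors. Lists of clock phases, glucocorticoid receptor targets and growth hormone targets were also added then. No sample was left out of the main comparisons.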

Results

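RNA sequencing counted gene transcripts in the livers of 24 mice, 6 normal controls and 18 animals of a steatohepatitis model, in which the liver holds fat and is inflamed. The labels treat the 18 model mice as 1 group and do not give the diet, duration, strain or sex. Each mouse gave 1 library. Total counts were 38.7 ± 6.02 M in controls (SD, n = 6) and 40.8 ± 7.17 M in model mice (SD, n = 18), and lay between 31.6 M and 58.4 M. The number of genes with at least 1 count was higher in model libraries, at 27908 ± 988 against 25168 ± 793. Mitochondrial transcripts took 6.03 ± 0.90% of counts in model mice and 5.00 ± 0.92% in controls. The design asks which genes, pathways and cell-type markers differ between the model and control livers, and how far the model mice differ among themselves.

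Gene expression differed widely between the groups. Of 17456 genes tested, 5445 were higher and 5035 lower in model livers (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Calls thus covered 60% of the genes tested, and the groups did not overlap at all for 1688 higher and 1051 lower genes. Counts of called list members near that share do not set a list apart. This holds for drug metabolism, bile acid, acute phase, fetal and immediate early genes below. Changes of at least 2-fold went mainly up, with 2838 genes higher and 600 lower. Among abundant genes, the highest fold changes were those of Cyp2b9 and Cyp2b13, cytochrome P450 genes expressed mainly in female liver, of Mmp12 and Gpnmb, a secreted protease and a membrane protein of lipid-laden macrophages, of Cidea, a lipid droplet protein, and of Ephb2, a receptor tyrosine kinase. Mmp12 (chromosome 9, 7344381 to 7369499, GRCm39) rose from 0.0933 ± 0.0421 to 50.1 ± 21.8 CPM, a log2 fold change of 9.04 (SE 0.65, adjusted p = 5.95e-11). Cidea (chromosome 18, 67476674 to 67500855) rose from 0.112 ± 0.057 to 49.4 ± 24.5 CPM, Gpnmb (chromosome 6, 49013480 to 49047863) from 0.155 ± 0.093 to 68.5 ± 40.2 CPM, and Ephb2 (chromosome 4, 136374850 to 136563299) from 0.0343 ± 0.0201 to 11.6 ± 6.81 CPM. Each of these 4 genes was higher in 18 of 18 model mice than in any control. Cyp2b9 rose from 0.0780 ± 0.147 to 73.8 ± 48.9 CPM. Cyp2b13 had 2 counts over the 6 controls and 6132 over the model mice, a ratio by library totals of 970 with a 95% counting interval from 268 to 8010. Its edgeR fold change with TMM factors was 579. The lowest fold changes were those of Hsd3b5, a steroid dehydrogenase gene of male liver, Serpina1e, an alpha-1-antitrypsin gene, and the major urinary protein genes Mup15, Mup11, Mup7 and Mup18. Hsd3b5 (chromosome 3, 98525950 to 98537568) fell from 80.6 ± 20.6 to 1.23 ± 2.26 CPM, a log2 fold change of -6.10 (SE 0.575, adjusted p = 4.94e-09). Serpina1e fell from 14610 ± 2546 to 377 ± 381 CPM, and the 4 Mup genes had log2 fold changes from -5.08 to -4.44. Cyp2b, Serpina1 and Mup genes have near-identical copies that can share reads, so the values of single members are uncertain. The balance of directions depended on scaling: 52.0% of called genes were higher with TMM factors, 62.8% with upper-quartile factors and 85.8% with library totals alone, which move the median log2 fold change of all genes from 0.012 to 0.106 and 0.342. Clock genes also differed between the groups, and with an index of them as a covariate, chosen after seeing the data, 3164 genes were higher and 2549 lower.

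Markers of macrophages rose in the model livers, with the highest median fold changes among the cell types listed. All 18 macrophage and monocyte genes were higher, with a median log2 fold change of 3.26. Lgals3, the galectin-3 gene, rose from 1.95 ± 0.617 to 59.7 ± 28.2 CPM, and Itgam, which encodes CD11b, from 0.0812 ± 0.0510 to 1.64 ± 0.795 CPM. Of 12 markers of lipid-associated macrophages, 11 rose, among them Trem2 (log2 fold change 5.62, SE 0.64) and Itgax (4.78), and Fabp5 did not pass the test (0.34). All 19 chemokine and cytokine genes tested rose, with a median of 2.89. Ccl7 had a log2 fold change of 5.33 (SE 0.477, adjusted p = 9.09e-10). Ccl3 had 2 control counts against 337 in model mice, a ratio by library totals of 53.3 with a counting interval from 14.6 to 442. With TMM factors its fold change was 32.5. Markers of resident Kupffer cells, the macrophages that live in liver sinusoids, went both ways: Cd5l, Folr2, Vsig4 and Clec4f rose, while Cd163 and C6 fell, and Timd4 had a log2 fold change of 0.53 (adjusted p = 0.40). C6 is a complement gene also expressed by hepatocytes. Cd163 was -0.36 with the clock covariate (adjusted p = 0.774). The mean log2 CPM of a list's members served as its score in each mouse. The macrophage score was 3.18 higher in model mice and the lipid-associated macrophage score 3.86 higher, in both cases above every control in 18 of 18 mice (exact permutation p = 7.43e-06, the smallest the design can give, adjusted 1.53e-05 over 35 lists). The Kupffer score was 0.79 higher (exact permutation p = 0.0123, adjusted 0.0143), and its set test did not pass (camera adjusted p = 0.297), though it did with fry (0.000688) and, at a mean log2 fold change of 2.02 against 1.01, with the clock covariate (0.0449). Camera gave adjusted p-values of 1.98e-11 for macrophages, 1.71e-06 for lipid-associated macrophages and 2.73e-10 for chemokines; with an estimated correlation the adjusted p = 0.271, 0.271 and 0.241.

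**Figure D1:**
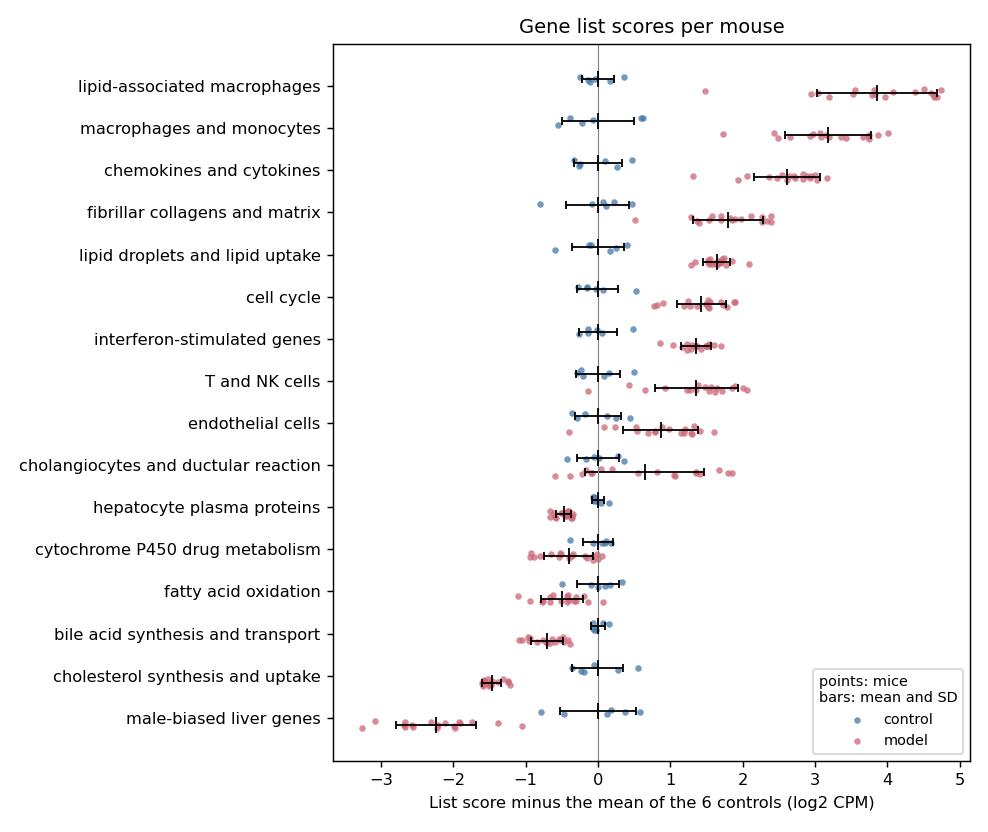
Scores of 16 gene lists in each mouse, as the mean log2 CPM of the list's tested members minus the mean of the 6 controls (x axis, log2 CPM). Points are mice, bars give the mean and SD of each group, and the lipid-associated macrophage score lies above every control in 18 of 18 model mice.

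Lymphocyte and neutrophil markers rose from low levels. Of 18 T and NK cell genes tested, 16 were higher, with a median log2 fold change of 1.43. The CD8 genes Cd8a (log2 fold change 2.77) and Cd8b1 (3.97) and the T-cell protease gene Gzmk (3.96) were above Cd4 (0.76) in size of change, a difference that was not tested. With the clock covariate the calls of Cd8a (2.19, adjusted p = 0.0825), Gzmk (3.79, adjusted p = 0.0653) and Cd4 (0.93, adjusted p = 0.225) were lost. That of Cd8b1 was kept (4.82, adjusted p = 0.012). Pdcd1, the gene for the checkpoint receptor PD-1, had 1 control count against 219 in model mice, a ratio by library totals of 69.3 with a counting interval from 12.3 to 2750. With TMM factors its fold change was 35. Of 9 B and plasma cell genes, 8 rose, among them Ighm, the IgM heavy chain gene, from 3.18 ± 1.00 to 18.3 ± 10.5 CPM, and Cd22 with a log2 fold change of 2.62. Of 8 neutrophil genes, 6 rose, including Csf3r, the G-CSF receptor gene, from 0.709 ± 0.439 to 4.61 ± 1.30 CPM, and Mmp8 (log2 fold change 2.68, SE 0.569). All 20 interferon-stimulated genes rose, with a median of 1.38, led by Ifit2 (2.67, SE 0.259) and Mx1 (2.18, SE 0.202). The scores of the 4 lists were higher by 1.36 for T and NK cells, 1.33 for B cells, 1.75 for neutrophils and 1.36 for interferon-stimulated genes (exact permutation tests, largest adjusted p = 0.000111). Camera's adjusted p was 0.000619, 0.00277, 0.00444 and 1.3e-09 in that order; with an estimated correlation the adjusted p = 0.419, 0.271, 0.305 and 0.241. With library totals alone the neutrophil list did not pass camera (adjusted p = 0.0571).

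Extracellular matrix genes rose, as did most stellate cell markers. Of 31 collagen and matrix genes, 29 were higher and none lower, with a median log2 fold change of 1.73. Col1a1, the main fibrillar collagen gene of scar tissue, rose from 1.75 ± 1.04 to 25.8 ± 11.9 CPM (log2 fold change 3.85, SE 0.468, adjusted p = 1.93e-07). Timp1, an inhibitor of matrix proteases, rose from 0.0485 ± 0.0413 to 3.08 ± 1.44 CPM. Of 16 stellate cell and myofibroblast genes, 12 rose, led by Vim (log2 fold change 2.27) and Dpt (1.98), and 13 when adjusted over the list alone. The contractile genes Acta2 (0.94, adjusted p = 0.0647) and Tagln (0.02, adjusted p = 0.948) did not pass. Of 14 endothelial markers, 11 were higher, or 12 adjusted over the list alone, with a median of 0.92, among them Flt4 (1.55) and Stab2 (1.46). Of 11 cholangiocyte genes, 4 rose, or 2 adjusted over the list alone, and Krt19 (0.23) and Krt7 (0.48), the keratins of bile ducts, did not pass. Krt23 had the largest change in that list, from 1.53 ± 0.399 to 13.6 ± 6.43 CPM, and Cftr a log2 fold change of 1.87 (SE 0.734, adjusted p = 0.0306). The Cftr call was lost without control 1, 3, 5 or 6 and at a threshold of 0.01. It was also lost with no filter (adjusted p = 0.0835), thinned counts (0.0514) and limma-voom (0.16). Scores were higher by 1.80 for matrix, 1.08 for stellate cells and 0.87 for endothelial cells (exact permutation tests, largest adjusted p = 0.00148), and by 0.65 for cholangiocytes (adjusted p = 0.0828). Camera's adjusted p was 1.3e-09, 0.000459, 0.00848 and 0.364; with an estimated correlation the adjusted p = 0.271, 0.305, 0.518 and 0.803. With library totals alone the endothelial list did not pass camera (adjusted p = 0.0645), while the cholangiocyte score did differ (adjusted p = 0.0227). The cholangiocyte list also passed fry (adjusted p = 0.0335).

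Genes of lipid storage rose while those of cholesterol synthesis fell. Of 16 lipid droplet and lipid uptake genes, 11 were higher and 4 lower, with a median log2 fold change of 1.61. Besides Cidea, Mogat1, an enzyme gene of triglyceride synthesis, rose from 0.646 ± 0.342 to 14.0 ± 3.61 CPM, Cd36, a fatty acid carrier gene, had a log2 fold change of 3.09 and Cidec of 2.52. Plin5 (-1.35), G0s2 (-1.48), Fitm2 (-0.62) and Pnpla2 (-0.53) fell; G0s2 inhibits the lipase that Pnpla2 encodes. Of 24 genes of cholesterol synthesis and uptake, 22 fell and none rose, with a median of -1.35. Idi1 fell from 8.18 ± 4.85 to 0.617 ± 0.172 CPM (log2 fold change -3.71, SE 0.197, adjusted p = 8.81e-14) and Sqle from 23.4 ± 10.8 to 3.17 ± 0.880 CPM (-2.88). The decrease took in Srebf2 (-1.03), the transcription factor gene that drives the pathway. Of 19 genes of fatty acid synthesis, 8 rose and 7 fell: Scd1 rose from 2321 ± 991 to 12940 ± 4269 CPM, Scd2 had a log2 fold change of 2.51 and Srebf1 of 1.46, while Acacb (-1.90), Acly (-0.53) and Me1 (-0.72) fell and Fasn did not pass (0.25, adjusted p = 0.299). Srebf1 was 0.76 with the clock covariate (adjusted p = 0.0691). Scores changed by 1.64 for lipid droplets, -1.47 for cholesterol synthesis and 0.28 for fatty acid synthesis (exact permutation tests, adjusted p = 1.53e-05, 1.53e-05 and 0.00481), each of the first 2 separating 18 of 18 model mice from all controls. The rise of the fatty acid synthesis score was lost with the median over members (adjusted p = 0.154). Camera's adjusted p was 0.0026, 9.73e-13 and 0.932; with an estimated correlation the adjusted p = 0.271, 0.241 and 0.964. With the clock index as a covariate the cholesterol list had a mean log2 fold change of -1.78.

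Genes of hepatocyte metabolism were mostly lower. Of 18 hepatocyte plasma protein genes, 14 fell, or 16 adjusted over the list alone, and none rose, with a median log2 fold change of -0.39. Alb, the albumin gene, fell from 113700 ± 23980 to 61860 ± 12340 CPM, and Hnf4a, a transcription factor of hepatocyte identity, from 1119 ± 221 to 589 ± 74.5 CPM. Of 18 bile acid genes, 10 fell, or 11 adjusted over the list alone, and 1 rose: Slco1a1, an uptake transporter gene, had a log2 fold change of -3.98 (SE 0.483), Cyp7b1 of -2.79 (SE 0.245) and Cyp8b1 of -1.86, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (0.29, adjusted p = 0.277). Of 25 fatty acid oxidation genes, 16 fell and Vnn1 rose; Acot1 had a log2 fold change of -1.90 and Cyp4a14 of -1.88, and Ppara did not pass (-0.19). With the clock covariate the Acot1 and Cyp4a14 values were -1.37 (SE 0.712) and -1.36 (SE 0.662), with wider errors that end the calls (adjusted p = 0.146 and 0.118). Of 20 drug metabolism genes, 10 fell and Cyp2a12 rose, a call lost with the clock covariate (adjusted p = 0.67); Cyp2d9 had a log2 fold change of -1.39 and Por, which passes electrons to the cytochromes P450, of -1.01. Cyp2c, Cyp2d and Cyp4a genes have close copies that can share reads, which leaves the values of single members uncertain. Of 15 methionine and one-carbon genes, 10 fell, or 11 adjusted over the list alone, and Bhmt rose, with Ahcy at -1.20. Score differences were -0.475 for plasma proteins, -0.707 for bile acids, -0.49 for fatty acid oxidation, -0.406 for drug metabolism and -0.428 for methionine metabolism (exact permutation tests, largest adjusted p = 0.0138). Camera's adjusted p was 1.04e-05, 0.00277, 0.00277, 0.00608 and 0.00277; with an estimated correlation the adjusted p = 0.241, 0.297, 0.518, 0.464 and 0.271. With library totals alone, the score differences for fatty acid oxidation (-0.16), drug metabolism (-0.08) and methionine metabolism (-0.10) no longer passed.

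Genes of glucose metabolism and insulin response went both ways. Of 14 genes, 8 fell and 4 rose. Pck1 (log2 fold change -2.06) and G6pc (-2.09), which encode the controlling enzymes of glucose production, fell, as did Igfbp1 (-2.67), a gene repressed by insulin, and Irs2 (-1.20). Pklr (0.80), a glycolysis gene, and the glucose transporter gene Slc2a2 (0.87) were among those that rose, and with the clock covariate these 2 values were 0.00 (adjusted p = 0.994) and 0.12 (adjusted p = 0.583). G6pc went from 665 ± 97.6 to 157 ± 67.4 CPM. The score fell (difference -0.44, exact permutation p = 7.43e-06, adjusted 1.53e-05), and the set test did not pass (camera adjusted p = 0.163, with an estimated correlation adjusted p = 0.518). The score difference was lost with library totals alone (-0.11) and with the median over members (-0.13), while the set test passed with library totals alone (adjusted p = 0.0391), with no filter (0.0328) and with fry (0.00141), and with the 2 settings chosen after seeing the data, the clock covariate (0.00426) and control 6 alone (0.00382).

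Most genes of the cell cycle, Nrf2 target and cell death lists rose, while acute phase and unfolded protein response genes went both ways. Of 26 cell cycle genes, 21 rose and 2 fell: Tpx2 rose from 0.190 ± 0.106 to 1.48 ± 0.596 CPM and Bub1 had a log2 fold change of 2.72, while Aurka (-0.69) and Rrm2 (-0.45) fell. Of 15 Nrf2 target and glutathione genes, 13 rose, among them Gsta1 from 0.809 ± 0.297 to 20.6 ± 9.39 CPM and Nqo1 with a log2 fold change of 1.51; the Gsta and Gstm members can share reads and are uncertain singly. Slc7a11, the cystine transporter gene, had 3 control counts against 433 in model mice, a ratio by library totals of 45.7 with a counting interval from 15.5 to 222. With TMM factors its fold change was 30.7. Of 13 cell death and inflammasome genes, 10 rose, including Nlrp3 (2.46), Casp4 (2.71) and Mlkl (1.58), and 1 fell. Of 12 p53 target genes, 6 rose and 2 fell: Eda2r had a log2 fold change of 4.42 and Phlda3 of 2.63, while Cdkn1a fell (-0.74). Acute phase genes split: Orm3 (4.47), Lcn2 (4.28), Saa1, Saa2, Saa3, Orm2 and Steap4 rose, Crp, Lbp, Itih3 and Itih4 fell, and 7 of 18 did not pass. In the unfolded protein response list of 15 genes, 3 rose and 8 fell, or 9 adjusted over the list alone. The risers were Trib3 (1.73), Chac1 and Ddit3, and the chaperone genes Hspa5 (-0.40), Creld2 (-0.83) and Sdf2l1 (-0.83) were among those that fell. Of 8 fetal liver and tumour marker genes, 4 rose, among them Ly6d from 1.655 ± 0.350 to 103.5 ± 58.5 CPM and H19 (4.21, SE 0.978), and Gpc3 fell (-1.10). With the clock covariate the values of Cdkn1a (0.27, SE 0.77), Crp (0.12, SE 0.174) and Gpc3 (0.00, SE 0.698) were no longer negative. The errors of Cdkn1a and Gpc3 are too wide to exclude their falls. The calls of Lbp (-0.11), Chac1 (0.31), Sdf2l1 (-0.17), Creld2 (-0.55) and Hspa5 (-0.27) ended at smaller values. Calls that also ended there were those of Saa1 (1.445), Saa3 (1.049), Itih3 (-0.33), Itih4 (-0.40) and Ddit3 (0.56). Scores were higher by 1.43 for cell cycle, 1.40 for Nrf2 targets, 1.26 for cell death, 0.86 for p53 targets, 1.01 for acute phase and 1.38 for fetal genes (exact permutation tests, largest adjusted p = 0.000124), and the unfolded protein response score differed by -0.16 (adjusted p = 0.167, or -0.345 and adjusted p = 0.0297 with the median over members). Camera's adjusted p was 6.02e-07, 0.000131, 0.00153 and 0.0216 for the first 4 lists; with an estimated correlation the adjusted p = 0.271, 0.241, 0.271 and 0.271. It did not pass for acute phase (0.188), fetal genes (0.142) or the unfolded protein response (0.159). Fry passed the acute phase (adjusted p = 0.00194) and fetal lists (adjusted p = 0.000152). The fetal list passed camera with no filter (0.0301) and with a filter of 1 CPM (0.0258). The unfolded protein response passed camera with no filter (0.0307), while its score turned to 0.17 with library totals alone. The p53 score was lost with the median over members (adjusted p = 0.0548), and the p53 list with library totals alone (adjusted p = 0.0583).

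Several lists fixed as checks also differed between the groups, among them clock genes and sex-biased liver genes. Clock genes moved in opposite blocks: Dbp (log2 fold change 2.68), Nr1d1 (2.13), Bhlhe41 (2.63), Per2, Per3 and Nr1d2 rose, while Arntl (-2.53), Cry1 (-2.27), Nfil3 (-2.14), Clock and Per1 fell, and 5 of 16 did not pass. Tef, among these 5 (0.20, adjusted p = 0.236), passed without control 6 (0.45, adjusted p = 0.00131) and with library totals alone (0.53, adjusted p = 0.00223), and turned negative with the clock covariate. Tef is part of the clock index, so an adjustment for that index cannot test it. An index of these genes, built after seeing the data, lay between 2.17 and 3.18 in the model mice. Among controls it lay between -1.85 and 0.173 in 5 mice and at 2.64 in control 6. Of 10 genes expressed more in male liver, 8 fell and 1 rose, with a median of -1.79, and Mup20, the most abundant, did not pass (-0.10, adjusted p = 0.769). Of 8 female-biased genes, Cyp2b9, Cyp2b13, Cyp2a4 (2.67) and Hao2 (4.79) rose, and Cyp2c40 (-3.72), Cux2 (-3.04) and Cyp17a1 (-2.26) were among the 4 that fell. Cyp2a4 was 1.09 with the clock covariate (adjusted p = 0.344). The male-biased score differed by -2.24 in 18 of 18 mice and the female-biased score by 1.43 (exact permutation tests, adjusted p = 1.53e-05 and 0.000124). Camera's adjusted p was 0.00123 for the male-biased list, or with an estimated correlation adjusted p = 0.271, and 0.898 for the female-biased list, which passed fry (adjusted p = 0.0329). Xist, expressed from the inactive X chromosome of females, did not exceed 0.21 CPM in any library, and the Y-linked gene Ddx3y was at least 11.8 CPM in each. Eif2s3y had a log2 fold change of -0.05 (adjusted p = 0.748), which turned positive with upper-quartile factors (0.05) and with library totals alone, where it passed (0.28, adjusted p = 0.0452), and of the 4 sex chromosome genes tested Kdm5d alone passed (0.31).

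Markers of other tissues were few. Of 4 erythroid genes, 3 fell, or 4 adjusted over the list alone, among them Alas2 (log2 fold change -0.31, adjusted p = 0.0353), whose sign turned with library totals alone (0.01) and whose call was lost with upper-quartile factors (adjusted p = 0.13), no filter (0.0881), a filter of 1 CPM (0.0537) and without control 1, 3 or 5. Of 4 mesothelial genes, Msln (-2.15) and Upk3b (-2.08) fell, and the other 2 did not pass, or rose when adjusted over the list alone. Of these, Gpm6a (0.72, adjusted p = 0.0652) also passed with upper-quartile factors (0.0435), library totals alone (0.0128), thinned counts (0.0478) and without control 2 or model 1, 8 or 11. With the clock covariate Msln was -0.66 (adjusted p = 0.71) and Upk3b -1.43 (adjusted p = 0.271), so neither call was kept. Of the adipocyte and pancreatic acinar lists a single gene each was tested: Cfd, the adipsin gene, rose from 0.620 ± 0.585 to 24.3 ± 22.9 CPM, and Cela2a, an elastase gene, fell from 0.511 ± 0.255 to 0.137 ± 0.0696 CPM. Among 10 immediate early and heat shock genes, Atf3 (2.27), Fosb (2.40) and Fos (1.49) rose, Dusp1 (-1.55), Ier2 (-0.45) and Hspa1b (-0.90) fell, and Jun did not pass (-0.12). The calls of Atf3 (1.02), Fosb (1.51) and Fos (0.95) ended with the clock covariate, as did those of Ier2 (-0.59) and Hspa1b (-1.06). Score differences were 0.33 for immediate early genes (exact permutation adjusted p = 0.144), -0.73 for erythroid (0.0111, lost with library totals alone), -0.70 for mesothelial (0.077) and 0.16 for sex chromosome genes (0.297). With library totals alone the immediate early (0.64, adjusted p = 0.012) and sex chromosome scores (0.49, adjusted p = 0.00653) passed, and with the median over members the mesothelial score did (-1.30, adjusted p = 0.0086). The clock list, whose blocks oppose each other, differed by 0.35 (adjusted p = 0.000813). None of these 5 lists passed camera (lowest adjusted p = 0.188), though the erythroid list did with library totals alone (0.0396), and it passed fry (adjusted p = 0.00675).

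Counted over lists, 30 of 35 scores differed between the groups, 21 higher and 9 lower (exact permutation over 134596 ways to choose 6 of 24 mice, adjusted p below 0.05). Camera with its preset correlation of 0.01 passed 22 of 35 lists, 15 up and 7 down, and 0 with a correlation estimated from the data, where fry, which asks whether a list's genes move on balance in 1 direction, passed 29. Adjusted over the list alone, the counts of members were unchanged in the lists where no second count is given. The spread of scores within a group differed for 4 lists. It was wider among model mice for cholangiocyte genes (SD 0.821 against 0.289, exact permutation adjusted p = 0.0371) and fetal genes (SD 0.681 against 0.323, adjusted p = 0.0371). It was wider among controls for clock genes (SD 0.290 against 0.093, adjusted p = 0.0371) and glucose genes (SD ratio of model to control 0.44, adjusted p = 0.0458). The 4 spread calls were lost when model 10 was left out, a choice made after seeing the data, and with the median over members.

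Model mice with more macrophage transcripts had more collagen transcripts. Among the 18 model mice the macrophage and matrix scores had a Pearson r of 0.94 and a Spearman rho of 0.94 (permutation p = 1e-05 for each, adjusted 4e-05 over 8 relations, the smallest p the resamples can give). The lipid-associated macrophage score had r = 0.95 and rho = 0.90 with matrix (permutation p = 1e-05 for each, adjusted 4e-05). Without the 2 mice farthest from the median of x, r was 0.89 and 0.90. The cholangiocyte score rose with matrix (r = 0.71, rho = 0.75, permutation p = 0.0007 and 0.00047, r = 0.69 without the 2 farthest mice). The drug metabolism score fell with matrix (r = -0.72, rho = -0.80, permutation p = 0.00054 and 0.00017, r = -0.71 without 2 mice) and with the macrophage score (r = -0.69, rho = -0.79, permutation p = 0.00112 and 0.00022, r = -0.75 without 2 mice). Cholangiocyte and drug metabolism scores each separated models 2, 3, 4, 9, 13, 15, 16, 17 and 18 from the other model mice without overlap. Their correlations over 18 mice may therefore reflect a difference between these sets, and relations within the sets were not tested. Matrix and lipid-associated macrophage scores leaned the same way. In both, all mice of this set but models 3 and 9 lay above every other model mouse. In the macrophage score all but models 3, 9 and 13 did. The same limit thus applies to the correlations of both macrophage scores with matrix. The other 3 relations no longer passed without the 2 farthest mice, whose removal also narrows the range of x. For stellate cells against matrix, r = 0.71 and rho = 0.54 (permutation p = 0.00104 and 0.0221) became r = 0.45 (p = 0.0786). For lipid droplets against fatty acid synthesis, r = 0.64 and rho = 0.51 (permutation p = 0.00492 and 0.0339) became r = 0.41 (p = 0.115), and 0.03 with the median over members in all 18 mice. For cell cycle against macrophages, r = 0.66 and rho = 0.67 (permutation p = 0.00263 and 0.00298) became r = 0.45 (p = 0.076). Over the 18 mice all 8 relations passed by Pearson r (largest adjusted p = 0.00492) and by Spearman rho (largest adjusted p = 0.0339). The labels give no batch. Split by library total into 2 sets of 9 mice, the macrophage relation had r = 0.91 in the deeper and 0.96 in the shallower libraries, and each of the 8 relations kept its sign in both. Both the deeper and the shallower libraries mix mice from either side of the separation above, so this split does not address it. Scores rose with the number of genes detected for matrix (r = 0.51, permutation p = 0.0275), lipid-associated macrophages (r = 0.50, p = 0.0328) and cholangiocytes (r = 0.51, p = 0.031), and r was 0.46 for macrophages (p = 0.0522). Model 10 had the lowest macrophage and matrix scores of the model mice.

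**Figure D2:**
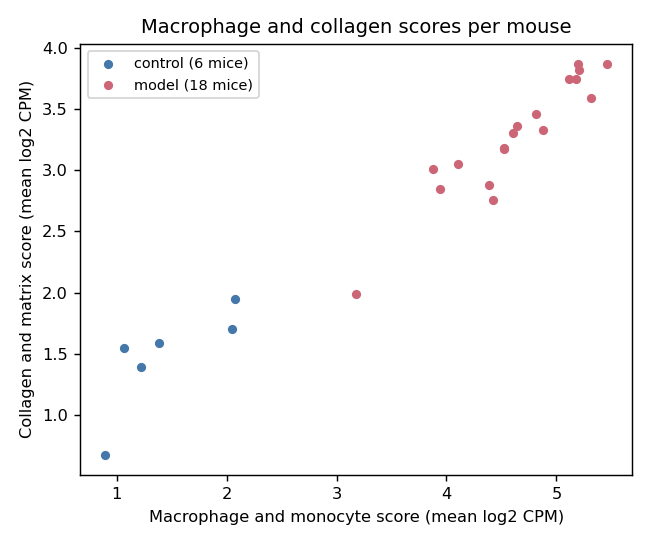
Macrophage and monocyte score (x axis, mean log2 CPM) against collagen and matrix score (y axis, mean log2 CPM), each point a mouse, for 6 controls and 18 model mice. The 2 scores rise together among model mice (r = 0.94), and model 10 lies lowest among them.

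**Figure D3:**
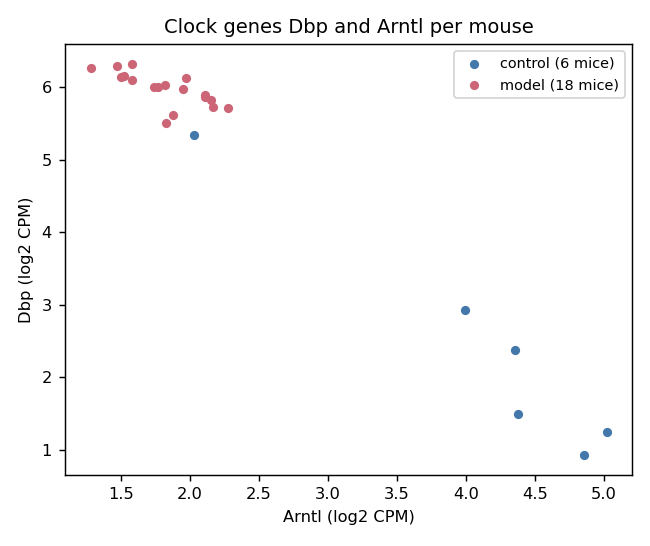
Arntl (x axis, log2 CPM) against Dbp (y axis, log2 CPM), each point a mouse, for 6 controls and 18 model mice. Control 6 lies beside the model mice, with Dbp at 5.34 and Arntl at 2.03, and the other 5 controls lie apart at higher Arntl.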

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

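The tests on cell-type shares, scaling, sex and the range of the clock index, and the clock covariate, were chosen after the result was seen; the comparison of each control with the others and the clock-output test were not. Among the 6 controls, a single mouse lay far from the other 5 in 7 of 112 results examined. Chance marks about 1 in 20, here 5.6, so the number of marks is close to what chance gives. Model mice are too many for this rule. Each value below is the mouse's gap to the nearest other control as a share of the group's range, against a limit of 0.625.

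Idi1 was highest in control 3 (4.17 against 2.39 to 2.90 log2 CPM, share 0.716). Igfbp1 was lowest in control 1 (5.96 against 7.18 to 7.72, share 0.695). Ly6d was highest in control 2 (1.27 against 0.58 to 0.72, share 0.797). Eif2s3y was lowest in control 5 (4.85 against 5.34 or more, share 0.648). Genes near the floor made up the rest. Ephb2 was lowest in control 4 (-4.34 against -3.63 to -3.21, share 0.629). Control 2 was highest for Pdcd1 (-3.75 against -4.34 in each other control, share 1.00) and for Mmp8 (-2.33 against -4.34 to -3.59, share 0.625).

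Markers of other cell types rose while hepatocyte genes fell. A lower share of hepatocyte RNA alone would raise the markers of all other cell types alike, but the macrophage score rose by 2.32 more than the endothelial score (exact permutation p = 7.43e-06), which argues against it as the whole account. Scaling is not the source of the macrophage rise, since the score minus the median of all tested genes, from which a library's factor cancels, rose by 2.99 (exact permutation p = 7.43e-06), nor of all of the hepatocyte fall, which shrank from -0.475 to -0.15 with library totals alone and still passed (exact permutation p = 7.43e-06). A change in the macrophages themselves, in number or in expression per cell, stays open, and whole tissue does not separate the 2.

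The clock difference may stem from the time of collection, which the labels do not give. If control livers were collected at scattered hours, clock-controlled genes outside the index (Usp2, Wee1, Lonrf3, Coq10b and Tspan4) would follow the index among controls, and they did (r = 0.93, exact permutation p = 0.0125; rho = 0.77, exact permutation p = 0.103; r = 0.85 without the 2 controls farthest from the median). The mean of the same genes was not higher in model mice (difference -0.21, exact permutation p = 0.216), as a shared shift of phase would need, and 1 of 6 controls, control 6, lay within the range of the model mice, where the index varied less (SD 0.28 against 1.67, exact permutation p = 0.000201). Collection time and an effect of the model on the clock cannot be told apart, since each group may have had its own hours. With the clock covariate the macrophage, matrix and cholesterol lists had mean log2 fold changes of 3.83, 2.48 and -1.78, against 3.28, 1.88 and -1.52 without it. These lists passed camera there, while the methionine list did not (-0.20, adjusted p = 0.0532). Camera with its preset correlation also passed 25 lists in a random division of the mice in which 0 genes were called. A camera pass therefore cannot decide whether a list's change outlasts the adjustment, and only the fold changes are compared here.

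Most male-biased genes fell while Cyp2b9 and Cyp2b13 rose. Female mice in the model group are excluded by the highest Xist level of 0.21 CPM. A general shift to the female pattern is opposed by 4 of 8 female-biased genes that fell. The male-biased list had a mean log2 fold change of -1.79 with the clock covariate, against -2.13 without it. This argues against the clock difference as the whole account, though the fit leans on control 6, the 1 control in the model mice's range. The model itself, which is the difference the design names, stays open as an untested biological explanation, and the partial fall of growth hormone targets does not decide it.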

How the results depend on the processing

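Counts over all genes stayed within 1.5 times the main count (10480 called, 5445 higher and 5035 lower) under most alternatives. Exceptions were library totals alone (9406 higher, 1562 lower, and 363 lower by at least 2-fold), the clock covariate (5713, as 3164 higher and 2549 lower) and control 6 alone (4487, as 2588 and 1899), the last 2 chosen after seeing the data. Control 6 alone leaves 1 library in an arm, which is assumed to vary like the model libraries. Counts of genes changed at least 2-fold moved with no filter (5266, of which 1174 lower, from 43568 genes tested), and the lower count with a filter of 1 CPM (387, from 13829 genes) and DESeq2 (1035). Where not stated, the cause was not tested. Balanced draws gave a median of 7365 genes. Leaving out each library in turn gave 10061 to 10630 genes, 5198 to 5474 higher and 4787 to 5175 lower, 3350 to 3591 changed at least 2-fold, and 22 lists each time.

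Replicate numbers are shared between the groups, but same-numbered mice did not deviate together: the 6 correlations lay between -0.185 and 0.11, and 1 of 6 controls correlated best with its own number (2000 genes). Replicates 7 to 18 exist only among model mice, so in the block design they stand alone and add nothing to the group effect. That fit therefore compares models 1 to 6 with the 6 controls, and its changes may stem from the smaller set of mice. With the replicate block, 7805 genes were called (7607 of them among the main calls) and 23 lists passed, the unfolded protein response among them (camera adjusted p = 0.0238). Mup20 was called lower (-0.343, adjusted p = 0.0409), Gpm6a passed (0.75, adjusted p = 0.0204), and the call of Alas2 was lost (adjusted p = 0.0965).

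Lists passing camera fell from 22 to 0 with an estimated correlation. No tested gene is in 2 lists, so leaving out shared members changes nothing. Changed score spreads fell from 4 to 0 with the median over members and to 0 without model 10. Relations that passed fell from 8 to 5 without the 2 farthest mice: stellate cells with matrix 0.45, lipid droplets with fatty acid synthesis 0.41 and cell cycle with macrophages 0.45. With the median over members the lipid relation was 0.03.

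Reversals of direction came mostly from values near 0. With library totals alone these were Mup20 (0.244), Eif2s3y (0.283), Jun (0.229), Alas2 (0.009) and the unfolded protein response (mean 0.195, score 0.170), and with upper-quartile factors Mup20 (0.003) and Eif2s3y (0.046). With the clock covariate they were Tef (-0.705) and the clock (-0.096), immediate early (-0.259) and mesothelial lists (0.253). Tef and most genes of the clock list are part of the index, so the covariate can test neither. Against control 6 alone they were Mup20 (0.354), Tef (-0.653), Alas2 (0.054) and the mesothelial list (0.896). Jun reversed with the block (0.198) and limma-voom (0.029). With the median over members the clock (-0.125) and immediate early scores (-0.025) reversed. Without control 3 Mup20 was 0.023 and Jun 0.087, without control 5 Jun was 0.072, and without control 4 Eif2s3y was 0.0. Over all mice left out in turn Mup20 ranged from -0.199 to 0.023, Eif2s3y from -0.138 to 0.0 and Jun from -0.275 to 0.087.

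Calls lost both with the clock covariate and against control 6 alone, with the direction kept, were those of Acot1, Cyp4a14, H19, Casp4, Bub1, Dpt, Mup7, Creld2 and Cftr (with the covariate, lowest adjusted p = 0.0508). Values with the covariate were still large for Bub1 (2.633, SE 1.045), Dpt (2.053, SE 0.884) and Casp4 (2.391, SE 0.93), whose errors widened, so a lost call does not show that the clock accounts for the change. Calls lost against control 6 alone were also those of Cyp2b13 (adjusted p = 0.101), Mup15 (0.0557), Mup18 (0.099), Pdcd1 (0.0783), Mmp8 (0.105), Cyp2d9 (0.0628) and Cfd (0.0677). Over all values of named genes, these included, 871 kept their call and direction, 35 became weaker and 6 stronger, and with mice left out 1712 kept, 7 weaker and 5 stronger. For lists 406 kept, 26 weaker (22 of them with the estimated correlation) and 17 stronger, and 840 of 840 kept with mice left out. For list scores 89 kept, 8 weaker and 5 stronger. Thinning to the smallest library gave 5164 higher and 4945 lower genes, so depth moved the counts little, while genes with 1 to 3 control counts stay uncertain in size.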

Other observations

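The hypotheses below were formed on these data. Chosen after the result was seen were the counts of genes and of camera lists over other splits of the mice and the clock covariate; the split count of list scores and the test of further glucocorticoid targets were fixed before their results.

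The genes in this paragraph lie outside the lists, were picked after their values were seen, and were not tested as groups. The MHC class II genes, which present antigens to helper T cells, rose: H2-Aa by a log2 fold change of 3.60 (SE 0.355), H2-Ab1 by 3.21 (SE 0.318), H2-Eb1 by 3.53 (SE 0.357), and Cd74, their invariant chain gene, by 3.44 (SE 0.343), from 19.8 to 214 CPM. Nrg1, a growth factor gene (5.34, SE 0.541), and Ntrk2, a neurotrophin receptor gene (7.39, SE 0.392), rose, and Egfr, a main growth factor receptor gene of hepatocytes, fell from 495 to 130 CPM (-1.93, SE 0.239). Ccnd1, the cyclin D1 gene, rose from 3.81 to 40.9 CPM (3.43, SE 0.175). Themis, a gene known from developing T cells, rose from 0.0833 to 23.7 CPM (8.12, SE 0.376), far above the T-cell markers Cd3e (0.732 CPM in model mice) and Trac (1.12 CPM).

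Growth hormone targets did not move as a block: Igf1 (-0.76, SE 0.108), Igfals (-1.04) and Socs2 (-1.49) fell, while Cish (0.67, adjusted p = 0.205), Onecut1 (0.61, adjusted p = 0.142) and Bcl6 (0.21, adjusted p = 0.525) did not pass. Glucocorticoid receptor targets were mostly lower, with 9 of 12 called lower and 2 higher: Zbtb16 had a log2 fold change of -3.47 (SE 0.238), Fkbp5 of -2.75 (SE 0.163) and Tsc22d3 of -1.32. A candidate explanation is lower glucocorticoid signalling in the model livers at collection. Of 6 targets whose values had not been seen, 3 were lower (Tat, Errfi1, Klf9), 2 were higher (Mt1, Mt2) and Sgk1 did not pass, short of the 4 lower that had been required, so the question stays open. Of the 12 targets, 8 were lower with the clock covariate, where the rises of Mt1 (0.46, adjusted p = 0.517) and Mt2 (0.48, adjusted p = 0.592) did not pass. The fall of Socs2 did not pass there either (-0.89, adjusted p = 0.404).

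Chance division of the mice was examined with 100 splits into 6 and 18, the real one included. For genes called, 1 of 100 splits gave as many as the real 10480 (highest other 3963, in a split that kept 4 controls together), and for genes changed at least 2-fold 1 of 100 gave as many as 3438 (highest other 1293), so chance is excluded for both. For list scores 1 of 100 gave as many as 30 (highest other 19), which excludes chance too. For lists passing camera, 8 of 100 splits gave as many as 22 (highest other 25), so chance is not excluded for that count: genes of a list vary together between mice, which a preset correlation of 0.01 leaves out.

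Model mice differed in how far they moved from controls. Over 26 pathway and cell type lists whose score changed, the median shift of a mouse, as a percentage of the mean model shift, lay between 54.2 in model 10 and 125.6 in model 15. Some scores also separated the model mice into sets. In models 2, 3, 4, 9, 13, 15, 16, 17 and 18 the cholangiocyte score was at least 1.577, against at most 1.305 in the others. The fetal score was at least 1.451 against at most 1.022, and the drug metabolism score at most 8.547 against at least 8.582. Principal components are the main axes along which libraries vary. The second, over log2 CPM of all tested genes, held 8.9% of the variance and split the model mice alike. It was at most -2.85 in this set and at least 12.86 in the other model mice. The split was thus not limited to these scores. The labels name no such sets, which were seen in the data and not tested.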
